A study of Bos taurus with 10 samples.

How the data were processed

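RNA sequencing was performed on white blood cells from the peripheral blood of 10 Holstein heifers, 5 recorded as pregnant and 5 as non-pregnant after transfer of an embryo produced by fertilisation in vitro. Pregnancy was diagnosed on day 21 after transfer. The day on which blood was drawn, the blood cell counts and any batch or date of library preparation are not given in the sources used here. Each library came from a separate heifer, so the spread between libraries of a group holds both animal and technical variation. Replicate numbers 1 to 5 within a group only name the animals and pair none of them.

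Per the labels' protocols, total RNA was isolated with a phenol-based reagent and passed an RNA integrity check, and libraries were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.4, HISAT2 and HTSeq, and the genome build ARS-UCD1.2. The annotation release, the library's strand type, the counting mode and the handling of reads that map to several places are not given in the sources used here. The deposited values are raw read counts per Ensembl gene ID, as the column name in the file headers and the whole-number values with unequal totals show. Each table held the same 27570 IDs and no row for unassigned reads. HTSeq counts leave near-identical gene copies and overlapping genes uncertain, and no molecular identifiers are described, so a limit set from a count of 0 covers counting error only. Intervals of the gene test rest on the spread between libraries, whatever its source.

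The files pair no ID with a gene name, and the gene table used here for names carried no Ensembl IDs, so 0 IDs were matched to a symbol. Gene names, positions, gene length and GC content were therefore not used here. The 28 gene lists fixed before the data were examined (interferon-stimulated genes, leukocyte, platelet and erythroid markers, antigen presentation, inflammation, steroid and prostaglandin signalling, and others) and the tests planned on them were not analysed here. For the same reason the rule for naming genes was reduced to the 2 IDs with the smallest p among those higher and the 2 among those lower in pregnant heifers, whether or not they passed the threshold.

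Gene IDs were kept by edgeR's filterByExpr with its minimum count of 10 and minimum total of 15, which left 14165 IDs holding between 99.8% and 99.9% of the counts of each library. Library sizes were scaled by TMM. Pregnant was compared with non-pregnant by edgeR's quasi-likelihood F test with robust dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its absolute value over the square root of F, and 95% intervals used the moderated degrees of freedom. Levels are given as CPM after TMM scaling, computed here from the deposited counts. Principal components and the share of variance between groups were computed on log2 CPM with a prior count of 2. Group differences in single values were tested by exact two-sided permutation over all 252 assignments of 5 of the 10 animals, for which the smallest p is 0.00794. The number of components examined was chosen after the data were seen.

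Pairs of libraries of a group were compared by a chi-square statistic over gene counts. The lowest was 22.2 per degree of freedom, so no pair agreed within sampling noise and all 10 libraries were kept as separate animals. The gene test was tested on simulated data: 5 sets of counts drawn from the means, dispersions and library sizes of these 14165 IDs for the comparison of pregnant with non-pregnant, each with 200 changed IDs. It called 10.4% of IDs changed 1.5-fold, 58.4% of those changed 2-fold, 74.8% of those changed 3-fold and 89.6% of those changed 4-fold, and 6.42% of its calls were false.

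Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom with sample quality weights, 3 other scalings, 2 other filters, non-robust dispersion, 2 other thresholds and leaving out each animal in turn. Alternatives chosen after seeing the data were principal components as covariates, removal of the 4 most abundant IDs, DESeq2 on the filtered IDs, leaving out the 2 libraries of lowest quality weight, and all alternatives for the principal components and the share of variance.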

Results

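The circulating leukocyte transcriptome was compared between heifers that carried a pregnancy after embryo transfer and heifers that did not. Each group held 5 animals, with 1 library per animal. Totals ranged from 14146666 to 22146290 counts per library, and averaged 18795083 ± 2690815 counts (SD, n = 5) in pregnant and 17002009 ± 2654697 counts (SD, n = 5) in non-pregnant heifers (exact permutation p = 0.317, two-sided). Between 17521 and 18446 gene IDs had at least 1 count in a library. A count of 0 allowed a level of up to 0.197 TMM-scaled CPM in the library with the smallest scaled size, from a limit of 3 counts. The 4 most abundant IDs together took between 7.27% and 14.0% of the counts of a library. The highest share was in pregnant heifer 2 and the next, 11.6%, in non-pregnant heifer 2.

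The series asks how pregnancy status bears on gene expression in white blood cells. Leukocyte profiles of heifers from different groups resembled each other as closely as those of heifers from the same group. Spearman's rho across genes averaged 0.971 over the 10 pairs of pregnant heifers, 0.972 over the 10 pairs of non-pregnant heifers and 0.971 over the 25 pairs of a pregnant with a non-pregnant heifer; genes are not independent replicates, and these values only describe the libraries. Pregnancy status took 11.7% of the variance of log2 CPM over the 14165 tested IDs, where groups drawn at random take 11.1% on average (exact permutation p = 0.365, one-sided for a larger share). The animals differed more along directions that crossed the groups. The first principal component held 24.7% of the variance and set pregnant heifer 5 and non-pregnant heifer 1 (scores 62.6 and 33.9) against non-pregnant heifers 3 and 4 (-36.3 and -34.4). The second held 19.7% and set pregnant heifer 2 and non-pregnant heifer 2 (52.3 and 41.1) apart from the other 8. Neither component differed detectably by pregnancy status, with exact two-sided permutation p of 0.421 and 0.889. The first component rose with the library total (Spearman's rho = 0.855, permutation p = 0.00281, adjusted 0.0112 over 8 relations; Pearson's r = 0.703, permutation p = 0.0190, adjusted 0.0761; r = 0.859 without the 2 libraries farthest from the median total). Within the groups, of 5 libraries each, r was 0.363 in pregnant and 0.990 in non-pregnant heifers, and was not tested. Both libraries that stood apart on the second component had the highest shares of counts in the 4 most abundant IDs. Since these 2 form a cluster of their own, no correlation over all 10 is given. Among the other 8 libraries the relation of this component to that share did not pass 0.05, with r = 0.666 (exact permutation p = 0.0740) and rho = 0.714 (exact permutation p = 0.0576). Without the 2 of them farthest from the median share, non-pregnant heifer 4 and pregnant heifer 3, r was 0.868 and was not tested. Pregnant heifer 3 ran against the relation (share 9.93%, score -18.9), so leaving it out favours a higher r.

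The third component, with 11.4% of the variance, separated the groups. All 5 pregnant heifers scored below all 5 non-pregnant heifers, with means of -13 ± 11 and 13 ± 19 (SD, n = 5 each; exact two-sided permutation p = 0.00794, the smallest this design can give). The adjusted p was 0.0317 over the first 4 components and 0.0714 over all 9, so the call depends on how many components are counted. The difference between the group means was -26.0 (pregnant minus non-pregnant). With 1 animal left out at a time, the p adjusted over 4 components exceeded 0.05 in 6 of 10 cases, up to 0.317. These were the cases without any one of the 5 pregnant heifers, or without non-pregnant heifer 2. Each refitted component was oriented to correlate positively with the original, so the direction of the difference tests little. The difference was -23.8 without pregnant heifer 3 (exact permutation p = 0.0794, unadjusted) and -22.0 without non-pregnant heifer 2 (exact permutation p = 0.151, unadjusted). Pregnant heifer 3 (-31.7) and non-pregnant heifer 5 (45.4) lay at the ends of this component. The groups came closest at pregnant heifer 5 (-3.63) and non-pregnant heifer 3 (0.472), a margin that was narrow beside the whole range.

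**Figure D1:**
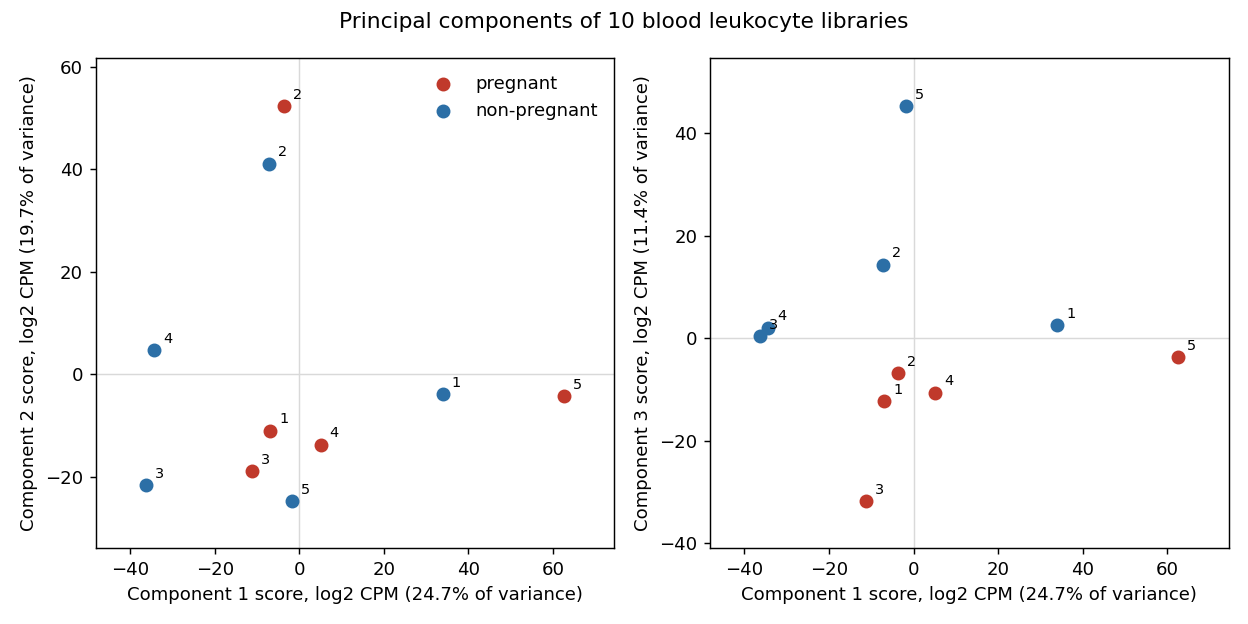
Scores of the 10 libraries on the first and second (left) and the first and the third (right) principal components of log2 CPM, with the share of variance on each axis; each point is 1 heifer, numbered within its group. The groups mix on the first 2 components, and all pregnant heifers lie below all non-pregnant heifers on the third.

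No gene ID differed between pregnant and non-pregnant heifers past the threshold. edgeR's quasi-likelihood test called 0 of 14165 IDs at an adjusted p of 0.05, and the lowest adjusted p was 0.651. At an unadjusted p under 0.05 there were 715 IDs, 318 with higher and 397 with lower values in pregnant heifers, against 708 expected if no ID differed. This number was 1074 without pregnant heifer 2 and 1591 with the first 2 components as covariates, still with 0 calls in either. limma-voom with sample quality weights also called 0 IDs, with 1357 at an unadjusted p under 0.05. DESeq2 called 5 IDs, 4 higher and 1 lower in pregnant heifers. The 2 groups did not overlap for 135 IDs (49 with all pregnant heifers above, 86 with all below), or 0.953% of those tested, where chance gives 0.794%.

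**Figure D2:**
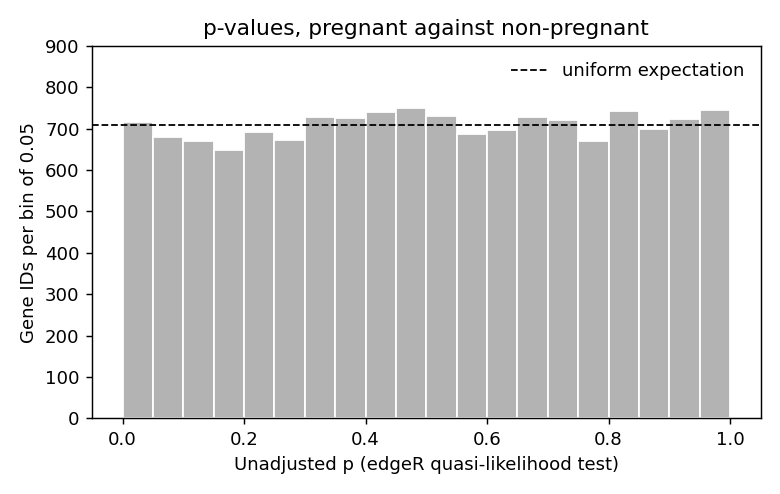
Unadjusted p-values of the 14165 tested gene IDs in 20 equal bins, with a dashed line at the count per bin expected if no ID differed. The lowest bin holds 715 IDs, beside an expected 708.

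The IDs with the smallest p are given as values, since none passed the main test. The files pair these IDs with no gene name. ENSBTAG00000019569 stood at 21.3 ± 7.12 CPM in pregnant and 45.9 ± 5.49 CPM in non-pregnant heifers (SD, n = 5 each), a log2 fold change of -1.10 (SE 0.20; edgeR adjusted p = 0.651). ENSBTAG00000016827 stood at 78.3 ± 6.61 CPM in pregnant and 114.7 ± 12 CPM in non-pregnant heifers (SD, n = 5 each), a log2 fold change of -0.55 (SE 0.12; edgeR adjusted p = 0.871). ENSBTAG00000048626 stood at 3.25 ± 1.74 CPM in pregnant and 0.733 ± 0.104 CPM in non-pregnant heifers (SD, n = 5 each), a log2 fold change of 2.13 (SE 0.40; edgeR adjusted p = 0.651). ENSBTAG00000008389 stood at 3.09 ± 2.42 CPM in pregnant and 0.435 ± 0.245 CPM in non-pregnant heifers (SD, n = 5 each), a log2 fold change of 2.84 (SE 0.61, edgeR adjusted p = 0.871). This ID ran from 0.985 to 5.94 CPM in pregnant heifers. Its 0.0956 CPM in non-pregnant heifer 1 lay below the limit of 3 counts in that library, 0.143 CPM, so its fold change rests partly on few counts. In each of the 4, no pregnant heifer's level overlapped the range of the non-pregnant heifers. These IDs were selected by their p, and the selection also favours large fold changes. DESeq2 called ENSBTAG00000019569 (adjusted p = 0.00448), ENSBTAG00000048626 (adjusted p = 0.00448) and ENSBTAG00000008389 (adjusted p = 0.00548), and left ENSBTAG00000016827 at an adjusted p of 0.0927 over all genes, which became 0.0392 on the filtered IDs. The other 2 IDs that DESeq2 called were both higher in pregnant heifers, and 1 of them was below the count filter of the edgeR test. On the filtered IDs DESeq2 called 9, and as many or more were called in 13 of 40 splits of the 10 animals into 5 and 5, the real one included.

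**Figure D3:**
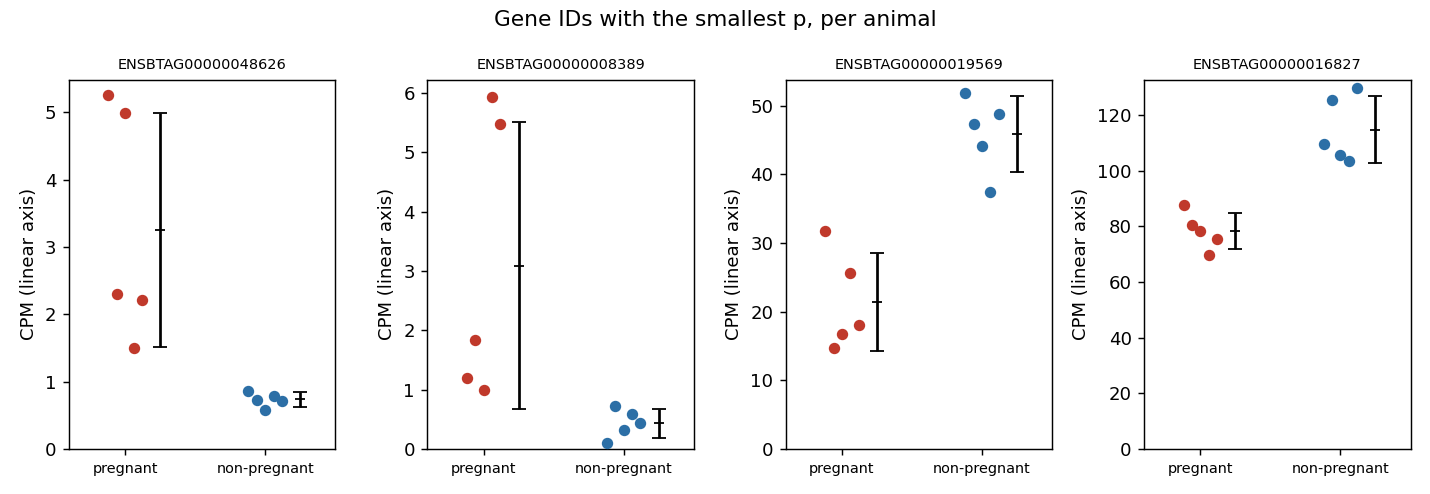
TMM-scaled CPM of the 2 gene IDs with the smallest p in each direction, 4 in all, on linear axes from 0. Each point is 1 heifer, and the bars show the group mean and SD (n = 5). The groups do not overlap in any of the 4 panels, while the adjusted p of the edgeR test is 0.651 or 0.871.

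The size of difference that these libraries leave open was set by the spread between animals and by the level of each gene. The biological coefficient of variation fitted over all IDs was 29.2%, and the median standard error of a log2 fold change was 0.21. The 95% interval lay wholly within a 2-fold change either way for 10858 of 14165 IDs (76.7%), and within a 1.5-fold change for 6226 (44.0%). Of the 6168 IDs with a mean log2 CPM between 4 and 7, 95.4% had an interval within a 2-fold change. Of the 4378 IDs between 1 and 4, 73.0% had, and of the 2095 IDs under a log2 CPM of 1, 15.2% had. For most IDs under a log2 CPM of 1, and for part of those above it, a change of 2-fold or more was thus not excluded. In counts simulated from these libraries, the test called 58.4% of IDs changed 2-fold and 10.4% of those changed 1.5-fold. There each ID was drawn independently and 200 were changed per set, which eases the Benjamini-Hochberg adjustment. The rates may thus not hold where IDs vary together or where few IDs change.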

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

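Of the tests in this part, the thinning of libraries was set before its result was seen, and the comparison of the first component with pregnancy status after. Dixon's rule was applied to 30 sets of 5 values, of which chance alone would flag about 1 in 20, and 3 were marked.

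The first component score of pregnant heifer 5 (62.6) lay far above those of the other 4 pregnant heifers, which ran from -11.2 to 5.02 (gap over range 0.780). Across all 10 libraries this component rose with the library total by rank (Spearman's rho = 0.855, permutation p = 0.00281). Pearson's r was 0.703 (permutation p = 0.0190, adjusted 0.0761), with 0.363 in pregnant and 0.990 in non-pregnant heifers. It was 0.859 without pregnant heifer 2 and non-pregnant heifer 1, whose totals lay farthest from the median. Pregnant heifer 2 ran against the relation (22146290 counts, score -3.67), so leaving it out favours a higher r. Pregnant heifer 5 had a lower total than pregnant heifer 2, 19992657 counts. Sequencing depth in itself is argued against: after every library was thinned to 14146666 counts, the new first component correlated with the old at r = 0.99993, and its rho with the original totals was 0.867. Pregnancy status is argued against as the whole cause, since 89.3% of the component's variance lay within groups, where status is constant. A smaller part stays open, as the exact permutation p of 0.421 excludes no group difference. A difference in leukocyte makeup or in RNA input between animals may also underlie the component and was not tested, as no gene name or cell count was used here.

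The second component score of pregnant heifer 2 (52.3) lay above those of the other pregnant heifers, which ran from -18.9 to -4.25 (gap over range 0.795). The same library had the highest share of counts in the 4 most abundant IDs, 14.0%.

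ENSBTAG00000049916 took 4.95% of the counts of pregnant heifer 2, and between 2.17% and 2.58% in the other pregnant heifers (gap over range 0.852); it is one of those 4 IDs.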

How the results depend on the processing

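The count of 0 IDs past an adjusted p of 0.05 was unchanged in 23 of 25 alternatives. An adjusted p of 0.10 and a 1.5-fold minimum could not change it (lowest adjusted p 0.651). The others included limma-voom, 3 scalings, 2 filters, non-robust dispersion and each animal left out in turn (0 to 0). They also included 1 or 2 components as covariates, removal of the 4 most abundant IDs, and omission of pregnant heifers 2 and 5 (lowest quality weights). The exceptions were DESeq2, with 5 IDs over all genes and 9 (3 higher and 6 lower in pregnant heifers) on the filtered IDs, the latter chosen after seeing the data; the cause was not tested. The 715 IDs at an unadjusted p under 0.05 became 1106 without a low-count filter, which tests more IDs, 1357 with quality weights, 1591 with 2 components as covariates and 1074 without pregnant heifer 2, and ranged from 560 to 1074 when single animals were left out. The share of variance between groups stayed between 11.3% and 15.5% over its 17 alternatives, with permutation p from 0.167 to 0.540. The group difference on the third component was -26.0 (pregnant minus non-pregnant). In its 17 alternatives the component was oriented to correlate positively with the original, so the kept sign tests little. The unadjusted permutation p stayed under 0.05 in 14, and the p adjusted over 4 components in 9. The difference ranged from -31.9 to -22.0 when single animals were left out. The end at -31.9, without non-pregnant heifer 5, belongs to a component correlated with the original at only 0.607. The difference was -25.0 without pregnant heifers 2 and 5 (exact permutation p = 0.161, fewer animals). The log2 fold changes of the 4 named IDs kept their sign in all 23 alternatives of the gene test. This says little, since these IDs were selected by p in the same libraries. Their groups do not overlap, so leaving out animals could not reverse the sign. No paired analysis was possible, as the labels link no animals between groups. The planned covariate of myeloid against lymphoid markers, the removal of erythroid, platelet, mitochondrial and ribosomal protein genes, and all tests of gene lists were not run, since they need gene names. Depth and group size limit the test most under a log2 CPM of 1 (median standard error 0.45). They also limit it above (0.17 between 4 and 7).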

Other observations

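Of the tests in this part, those on the number of IDs at an unadjusted p under 0.05 and on DESeq2 calls were set before their results were seen, and the others after. Some gene IDs were either well expressed or without counts, depending on the animal. In 4 tested IDs every library held either at most 3 counts or at least 5 CPM, with at least 2 libraries of each kind. All 4 are named here after their values were seen. ENSBTAG00000036061 had 0 counts in pregnant heifers 1 and 4 and non-pregnant heifers 3 and 5, and ENSBTAG00000011240 had at most 2 counts in non-pregnant heifers 1 and 4. The largest gaps were those of ENSBTAG00000009656 and ENSBTAG00000038128, which had 0 counts in the same 2 libraries, non-pregnant heifers 3 and 5. In the other 8 heifers ENSBTAG00000009656 ran from 140.0 to 414 CPM and ENSBTAG00000038128 from 40.8 to 147 CPM. Against a limit of 3 counts per library (0.193 TMM-scaled CPM in non-pregnant heifer 3), the lowest of those levels was at least 725-fold higher for the former and at least 211-fold higher for the latter.

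Too little depth is argued against as the source of the zeros of these last 2 IDs, since at the lowest level of the other 8 heifers the 2 libraries would have held at least 633 counts of either ID. Their absence in 2 of 5 non-pregnant and 0 of 5 pregnant heifers gave a two-sided Fisher's exact p of 0.444, the smallest that 2 absences among these 10 animals can give, so a link to pregnancy status can be neither shown nor excluded. A candidate explanation is a deletion or divergent allele, carried by some animals, that covers both IDs or keeps their reads from mapping to the reference. It was not tested, as positions and genotypes were not used here.

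The real split was set against other splits of the same 10 animals, with 100 of the 126 possible splits into 5 and 5 drawn. For edgeR's 0 calls this tests nothing, since 100 of 100 splits reach a count of 0 by construction; 7 of the other splits had at least 1 call, and the highest had 9. The 715 IDs at an unadjusted p under 0.05 were matched or exceeded in 36 of the 100 splits, the real one included, with a highest other count of 2671. DESeq2's 9 calls on the filtered IDs were matched or exceeded in 13 of 40 splits, the real one included, and the highest other count was 508, so chance is not excluded for them. The splits with several times the real count point to a structure of the samples. The count went with how far a split parted the animals on the first component (r = 0.712) and on the second (r = 0.459). The 100 splits share animals and are not independent. The relation is also partly built in, since these components are the directions of largest variance of the same libraries. The split with 2671 IDs set first-component scores of -36.3 to -1.82 against -7.22 to 62.6. What underlies that component was not settled.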
